A study of Mus musculus with 6 samples.

How the data were processed

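Labelled RNA from 6 samples of in vitro differentiated mouse adipocytes, 3 control and 3 Nr2f2-deleted, was hybridised to whole-transcript arrays. The deposited values of both tables are log2 signals, and the submitters' processing notes name Transcriptome Analysis Console. Its version, the summarisation method and the genome build are not given in the sources used here. Both tables end at a log2 signal of 19.93.

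The first table holds 28846 probe sets, of which 22206 transcript probe sets were used and 6640 control probe sets were left out of the tests. Its probe sets are not paired with gene names in the sources used here. The second table gives a gene symbol and 1 log2 value per array for 1757 rows. It was deposited as a selection without a stated rule, and its rows follow the difference between group means. Only 4 of its rows have all 6 values in the first table at 2 decimals, so the tables differ in how their values were made, in a way not given in the sources used here, and each was tested on its own. Of its rows, 81 carry several symbols, 3 carry a date in place of a symbol and 1673 carry 1 symbol, which gives 1665 genes. A mouse reference gene table of assembly GRCm38.p6 was used for names alone: 1551 symbols were current, 69 matched through a synonym and 45 did not match.

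Groups came from the sample labels. Differences (deleted minus control) were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, no block, all 6 arrays, no filter on dim rows). P-values were adjusted by the Benjamini-Hochberg method within each table, with a threshold of 0.05. Gene lists were tested with camera at a preset correlation of 0.01 on 1 row per gene, the one with the highest mean, and adjusted over the lists with at least 5 measured genes. The design named the first table for all tests. Lists and named genes were run on the second instead, since it alone has gene names, and an adjusted p there covers selected rows. That selection covered the lists unevenly. It held 33 of 36 electron transport chain genes and 13 of 20 TCA cycle genes, but 0 of 35 nuclear receptors. Camera compared each list with the other selected rows, not with all genes on the array.

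The tests, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule takes the 12 largest differences in each direction among rows of 1 symbol, without predicted genes and small RNAs, that passed and did not overlap between groups. Open places are filled by the largest differences with an unadjusted p under 0.01 and no overlap. It adds Nr2f2 and 10 further genes whatever their values, and up to 4 members with the smallest p in each described list. Lists described are those called and 7 others named in advance. Leaving out the 4 rows at the upper limit on all arrays was tried after list results had been seen. It gave smaller p-values for the called lists and is kept as an alternative, with those rows included as the design has it.

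The fits were tested on simulated data with the means and spreads of the real rows and 200 changed rows, over 10 draws. For this comparison on 22206 probe sets, 1.4% of 2-fold and 81.9% of 8-fold differences were recovered. On 1757 rows the shares were 37.3% and 88.1%. Simulated lists without correlation or shift gave a called list in 5% of draws.

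Alternatives were a replicate block, quantile normalization, median centring, filters on dim rows, other eBayes settings, array weights, other thresholds, each array left out, the other table, and for lists an estimated correlation, fry, row means and brighter members. Alternatives chosen after seeing the data were the brightest 10% of probe sets, removal of a trend with signal, rows that join a gene with small RNAs, and leaving out rows at the upper limit.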

Results

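RNA was measured on 6 arrays from adipocytes differentiated in culture from mouse subcutaneous adipose stem-like cells. The cells came from pups at postnatal day 12 and carried floxed alleles of Nr2f2, which encodes a nuclear receptor of the COUP-TF family. After 24 hours in culture, 3 samples received an adenovirus carrying GFP alone (control) and 3 received an adenovirus carrying Cre recombinase and GFP (Nr2f2-deleted). A recovery of 2 days preceded 10 days of differentiation. The comparison asks how loss of Nr2f2 in the stem-like cells alters the adipocytes they form. Values were read from 2 tables of log2 signals. One covers 22206 transcript probe sets without gene names, and the other gives gene symbols for 1757 rows. The median signal per array lay between 5.45 and 5.48 in the first table and between 5.82 and 5.91 in the second. Between 31.3% and 41.6% of transcript probe sets on an array were brighter than the brightest background probe set of that array, and the number of arrays limits the precision. The labels call the samples biological triplicates and do not say which animals they came from, so p-values measure the spread between these samples.

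No single gene passed the adjusted threshold. Mean signals for TCA cycle, respiratory chain and glycolysis genes were lower on the deleted arrays than on control replicates 1 and 2, while control replicate 3 lay near the deleted arrays. The calls of these lists at camera's preset correlation were lost with an estimated correlation (adjusted p = 0.519 for each). Csf1, Timp1 and Naca had higher means in the deleted cells, and were chosen among genes whose groups do not overlap. Csf1, a growth factor of macrophages, was at 4.86 ± 0.23 in controls and 7.27 ± 0.42 in deleted cells (log2 signal, mean ± SD, n = 3), a log2 difference of 2.41 with a standard error of 0.28 (limma adjusted p = 0.0979). Its control mean lay below 6.73, the 95th percentile of 66 olfactory, vomeronasal and taste receptor genes in the same table, which stand for unexpressed genes, so the size of the difference depends on the background. The same holds for the control means of Timp1 and Naca. The receptor genes were picked after values had been seen, and their rows belong to a selected table. In the probe-set table, whose values were made differently, the brightest background probe set of an array lay lower, between 5.67 and 5.94. Timp1, an inhibitor of matrix metalloproteinases, differed by 1.56 ± 0.19 (SE; adjusted p = 0.0979). Naca, a subunit of the nascent polypeptide-associated complex, differed by 2.54 ± 0.28 (SE; adjusted p = 0.0979). Idh3a, a catalytic subunit of the TCA cycle enzyme isocitrate dehydrogenase, was at 10.53 ± 1.54 in controls and 7.31 ± 0.67 in deleted cells (mean ± SD, n = 3), a difference of -3.22 with a standard error of 0.80 (adjusted p = 0.213).

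In the probe-set table, limma called 0 probe sets higher and 0 lower at an adjusted p under 0.05, and the smallest adjusted p was 0.0651. At an unadjusted p under 0.05 there were 1098 probe sets, against 1110.3 from chance alone. The groups did not overlap at 10.2% of probe sets, where chance gives 10%. In the gene table, 0 rows passed in either direction, with a smallest adjusted p of 0.0979, and 340 rows had an unadjusted p under 0.05 against 87.85 from chance. The groups did not overlap at 25.4% of its rows. The gene table is a selection made by a rule not given in the sources used here, and its rows run in order of the difference between the groups, so the surplus cannot be separated from that selection. Without control replicate 3, 6 probe sets were higher and 7 lower, and among gene table rows 9 were higher and 18 lower.

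Nr2f2 itself was not analysed here, because no row of the gene table carries its symbol and the probe sets have no gene names in the sources used here. The deletion could therefore not be checked from these sources. For the same reason Cidea, Ppargc1a, Prdm16, Pparg and Nr2f1 were not analysed.

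Among genes with no overlap between groups and an unadjusted p under 0.01, the 12 with the largest differences in each direction were taken, and none of the 24 passed the adjusted threshold. Some genes outside that filter differed by more, such as Uqcrc1 (-3.75). On the higher side, the log2 differences were 2.35 for Prelid1, which carries lipid between mitochondrial membranes, 1.94 for the lysosomal protease Ctsz, 1.68 for the sterol desaturase Sc5d and 1.58 for the actin-binding protein Lasp1. They were 1.51 for Itm2c and 1.36 for the proton pump subunit Atp6v0d1. For the kinase Rps6ka6, the oxidoreductase Aifm2 and the scramblase Xkr8, both group means lay below the receptor genes' 95th percentile, so no difference is given. Of the 12 genes on the higher side, 10 had a control mean below that percentile, all but Prelid1 and Sc5d, and their differences depend on the background. On the lower side, differences were -2.35 for Acadvl, which starts the oxidation of very long-chain fatty acids, -2.28 for the cytochrome oxidase subunit Cox7a2 and -2.14 for the adipocyte phospholipase Pla2g16. Ero1l, an oxidase of the endoplasmic reticulum, differed by -2.09, the glycolytic enzyme Pgk1 by -2.08, and Lipe, the hormone-sensitive lipase, by -2.06. The remaining differences were -1.99 for the ATP synthase subunit Atp5g2, -1.91 for Ogdh of the TCA cycle, -1.81 for the ubiquitin-activating enzyme Uba1, -1.72 for the proteasome subunit Psmb7 and -1.70 for Dlat of the pyruvate dehydrogenase complex. The deleted means of Ogdh and Psmb7 also lay below the percentile. Apart from Uqcrc1, the differences given in this paragraph had standard errors between 0.21 for Lasp1 and 0.62 for Acadvl.

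**Figure D1:**
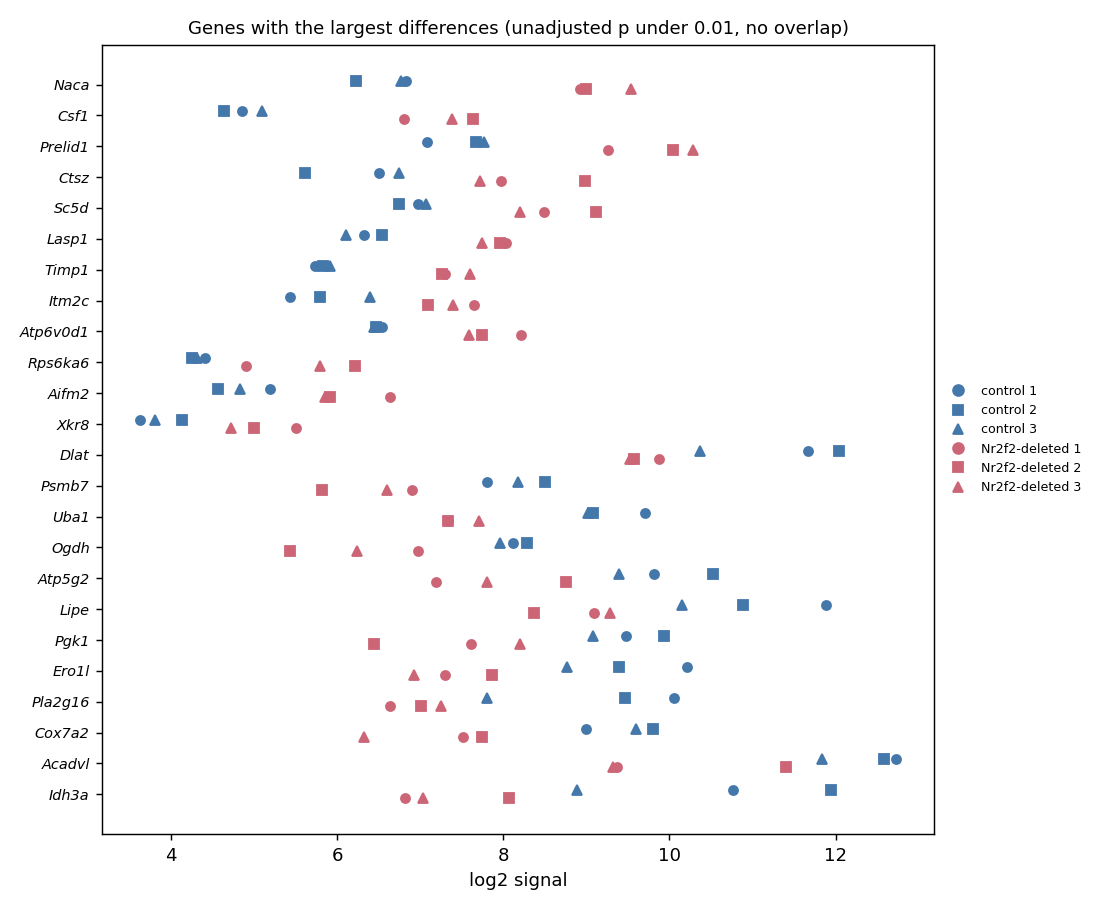
Log2 signal (horizontal axis) of the 24 genes with the largest differences among those with an unadjusted p under 0.01 and no overlap between groups, one gene per line; blue points are the 3 control arrays, red points the 3 Nr2f2-deleted arrays, and the marker shape gives the replicate number. The groups do not overlap for any gene shown, which was a condition of choosing them, and control replicate 3 (blue triangle) is the control nearest the deleted arrays for 10 of the 12 lower genes and 6 of the 12 higher genes.

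Of 42 gene lists fixed before the data were examined, 12 had at least 5 measured genes, and limma's camera with its preset correlation called 5 of them. None of the 5 calls held when the correlation between list members was estimated from the arrays (adjusted p = 0.519 with an estimated correlation for each list). That equal value comes from the adjustment over lists, and uncalled lists share it. The test is also stricter in itself: simulated lists without correlation or shift gave a call in 0% of draws, against 5% at the preset. The estimated correlation rests on the spread within groups, and control replicate 3 lay apart from the other controls. The SD of the TCA cycle list mean was 1.16 in controls and 0.16 in deleted cells. For the cytokine list, which went the other way, the SDs were 0.06 and 0.29. The estimate was not made without control replicate 3. The TCA cycle list was lower, with a median log2 difference of -1.63 and all 13 measured members lower in the deleted cells (camera adjusted p = 0.000372, and adjusted p = 0.519 with an estimated correlation). 0 members passed over all genes and 3 passed adjusted over the list alone, which were Idh3a, Ogdh and Dlat. Sdhb, a subunit of succinate dehydrogenase, differed by -1.87 ± 0.61 (SE). The electron transport chain list had a median of -0.87, with 28 of 33 members lower (adjusted p = 0.00125, and adjusted p = 0.519 with an estimated correlation). 0 of its members passed over all genes, and adjusted over the list alone 1 passed, the complex I subunit Ndufs8 (-1.40 ± 0.25, SE), whose deleted mean lay below the receptor percentile. Uqcrc1 of complex III differed by -3.75 ± 1.10, Sdhb by -1.87 ± 0.61 and Ndufv2 of complex I by -1.75 ± 0.57 (SE). In the glycolysis and glucose uptake list, all 12 measured members were lower, with a median of -0.78 (adjusted p = 0.00401, and adjusted p = 0.519 with an estimated correlation), and 0 passed over all genes or adjusted over the list alone. Its members with the smallest p were Pgk1, the pyruvate kinase gene Pkm (-1.53 ± 0.50), the lactate dehydrogenase gene Ldhb (-1.83 ± 0.74) and Gpi1 (-1.76 ± 0.74; SE). The deleted mean of Ldhb lay below the receptor percentile.

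The extracellular matrix list was higher, with a median of 0.75 and 16 of 20 members higher (adjusted p = 0.0156, and adjusted p = 0.519 with an estimated correlation). Control replicate 3 had the highest mean of this list among the 6 arrays, 9.28 against 8.24 to 8.77 for the deleted arrays. 0 members passed over all genes, and adjusted over the list alone 1 passed, Timp1. The proteoglycan Dcn differed by 1.98 ± 0.84, and Thbs2, with a control mean below the receptor percentile, by 1.04 ± 0.51 (SE). Both means of Vcan lay below it, so no difference is given. The inflammatory cytokine and chemokine list had 5 measured members, of which 4 were higher, with a median of 0.39 (adjusted p = 0.0363, and adjusted p = 0.519 with an estimated correlation). 0 passed over all genes, and adjusted over the list alone 1 passed, Csf1. The chemokine Cxcl12 differed by 1.14 ± 0.44 (SE). For 3 of the 5 members, Ccl8, Ptx3 and Il1b, both means lay below the receptor percentile, and the list's median is the difference of Ccl8. The list was left with fewer than 5 members when those below the median signal were left out.

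In simulated tables with no shift and members correlated as estimated, the preset correlation called at least 1 of the 12 lists in 93% of 100 draws. Each simulated list varied on its own, and the TCA cycle list alone was called in 42%. A call at the preset correlation thus does not separate a shift between groups from variation shared by the members of a list.

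Control replicate 3 stood apart from the other controls and moved with the metabolic and matrix lists. On the first principal component of the gene table, which held 47.1% of the variance, it scored 11.02, against -23.97 and -27.41 for the other controls and 11.19 to 16.02 for the deleted arrays. List means of control replicate 3 lay within the range of the deleted arrays, or beyond it on the far side from the other controls, for the electron transport chain, fatty acid oxidation, thermogenesis, mature adipocyte, lipogenesis, NRF2 and extracellular matrix lists. In the cytokine list it lay among the controls, at 5.78 against 5.71 and 5.84 for them and 6.28 to 6.85 for the deleted arrays. Members of that list differed in this. For Csf1 control replicate 3 was at 5.10, against 6.81 to 7.63 for the deleted arrays. For Cxcl12 it was at 7.86, within the deleted arrays' 7.85 to 8.46 and above the other controls at 6.27 and 7.20. The remaining members had both means below the receptor percentile. On the second component of the gene table (16.3% of the variance) control replicate 3 scored 22.35. That was apart from the deleted arrays at -11.86 to -3.08 and also from the other controls at -1.28 and 0.36. In the probe-set table its scores lay within the range of the deleted arrays on the first component (28.17, against 11.23 to 35.18) and on the second (-13.79, against -15.18 to 20.53). On that second component the other controls scored -40.17 and 53.03, so control replicate 3 also lay between them. Without control replicate 2, 1 list was called, the TCA cycle, and without control replicate 3, 6 were called.

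**Figure D2:**
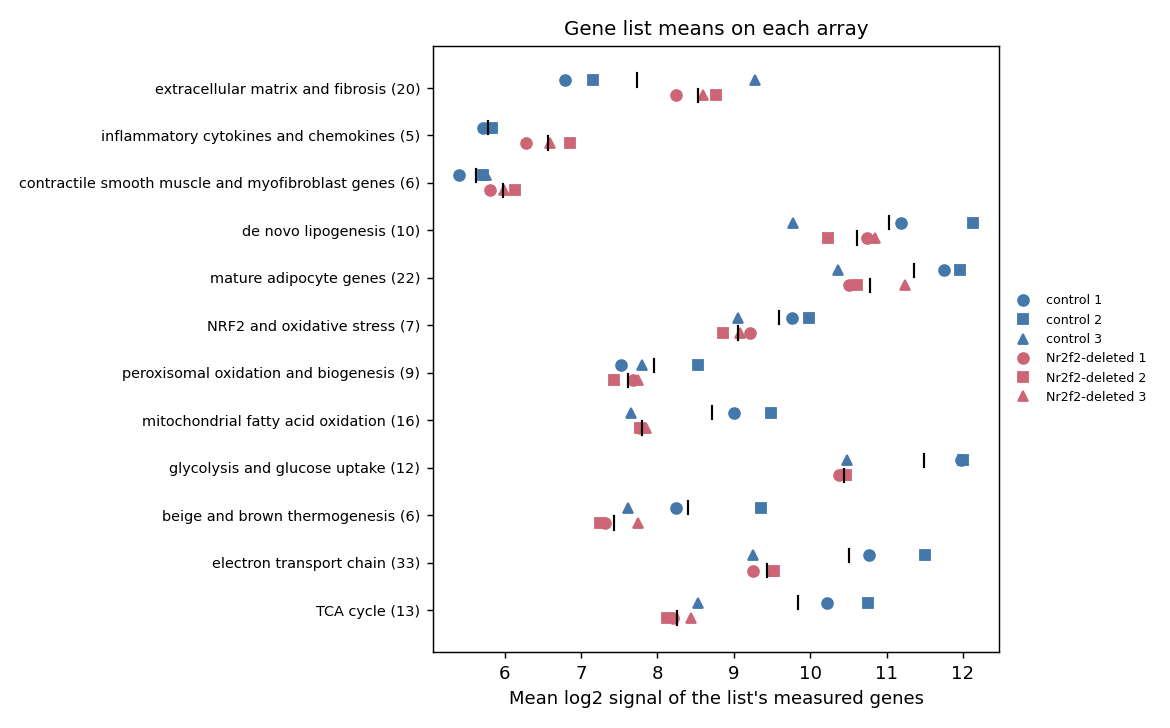
Mean log2 signal of the measured genes of each list (horizontal axis) on each array, with the number of measured genes in brackets; blue points are control arrays, red points Nr2f2-deleted arrays, marker shape gives the replicate number, and black bars are group means of 3 arrays. Control replicate 3 (blue triangle) lies near the deleted arrays in the metabolic lists and above them in the extracellular matrix list.

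**Figure D3:**
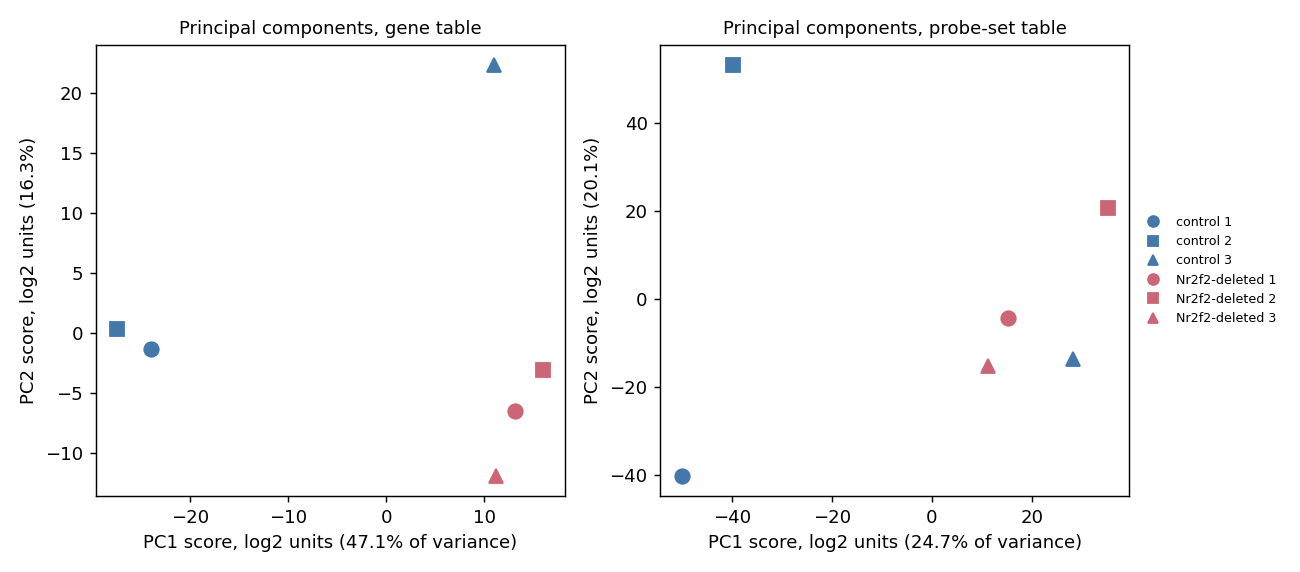
Scores of the 6 arrays on the first (horizontal) and second (vertical) principal components of each table, in log2 units, with group by colour and replicate by marker shape. Control replicate 3 has a score of 11.02 on the first component of the gene table, on the side of the deleted arrays.

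With all 6 arrays and the main settings, adipocyte and thermogenic genes gave no called list. Without control replicate 3, the fatty acid oxidation list (median -1.31) and the mature adipocyte list (median -0.67) were called. Fatty acid oxidation was also called under some other alternatives, given below. The beige and brown thermogenesis list had 6 measured members of 27, with a median of -0.80 (camera adjusted p = 0.168). Fabp3 differed by -2.83 ± 1.12, Cox7a1 by -2.16 ± 0.78 and Cpt1b by -1.03 ± 0.62 (SE), all with deleted means below the receptor percentile. Cox8b differed by -0.57 ± 0.50 (SE), and by -0.92 without control replicate 3. Ucp1, the uncoupling protein of thermogenic fat, was at 6.09 ± 0.03 in controls and 6.17 ± 0.92 in deleted cells (mean ± SD, n = 3), within the levels of the receptor genes, whose 95th percentile was 6.73. Mitochondrial fatty acid oxidation genes had a median of -0.73, with 14 of 16 members lower (adjusted p = 0.0851), among them Hadhb (-2.36 ± 0.80), Hadha (-1.89 ± 0.72) and Hadh (-2.13 ± 1.09; SE) beside Acadvl. Hadh, with a deleted mean below the receptor percentile, differed by -3.31 without control replicate 3. In the mature adipocyte list, the median over 22 members was -0.35 (adjusted p = 0.168). The lipid droplet protein Plin1 differed by -1.27 ± 0.26, and the lipase Pnpla2 by -1.77 ± 0.94 (SE), beside Lipe. Both means of the hormone gene Lep lay below the receptor percentile, so no difference is given. Adipoq, which encodes adiponectin, was at 9.12 ± 1.51 in controls and 10.36 ± 1.57 in deleted cells (mean ± SD, n = 3; adjusted p = 0.541), and its difference ran from 0.55 to 2.11 with an array left out. Fabp4, the adipocyte fatty acid-binding protein, was at the upper limit of the scale on all 6 arrays, so it has no fold change here. Cebpa, an adipogenic transcription factor, differed by -1.39 ± 0.54 (SE; adjusted p = 0.248), and by -0.86 without Nr2f2-deleted replicate 3. In each of these lists, 0 members passed over all genes and 0 adjusted over the list alone.

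De novo lipogenesis genes had a median of -0.34 over 10 members (camera adjusted p = 0.869), and 0 passed over all genes or over the list alone. Thrsp differed by -3.27 ± 1.47 and Insig1 by 1.33 ± 0.81 (SE), and Acly by -0.99, less than its standard error. Without control replicate 3, Insig1 differed by 0.745. Both means of Acss2 lay below the receptor percentile. Of 26 adipose stem cell and progenitor markers, 3 were measured, too few for a list test. Fn1 differed by 1.68 ± 1.62 (SE), and by 3.55 without control replicate 3. Both means of Wnt10b and of Pdgfrb lay below the receptor percentile. Among the other tested lists, contractile genes had a median of 0.34 (adjusted p = 0.168), and 5 of 6 members had both means below the receptor percentile. The NRF2 and oxidative stress list had a median of -0.46 (adjusted p = 0.418), and peroxisomal genes had -0.46 (adjusted p = 0.515). Without control replicate 3 these medians were 0.35, -1.16 and -0.41, and none of the 3 lists was called. Of the 30 lists with fewer than 5 measured genes, 11 had none, among them the endothelial and pericyte markers.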

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

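The alternatives chosen after the data were seen were the brightest 10% of probe sets, removal of the trend with signal, rows joining a gene with small RNAs, and rows at the upper limit left out. Of the 388 probe sets and 134 gene table rows with an unadjusted p under 0.05 and at least a 2-fold difference, 195 and 43 were higher. At an adjusted p under 0.1 there were 2 probe sets and 4 rows, with trend and robust eBayes 1 of each, and with quantile normalization 4 rows. Leaving out each array gave 0 to 13 probe sets and 0 to 27 rows, both highest without control replicate 3. With the replicate number as a block, 0 probe sets and 0 rows passed and 6 lists were called, fatty acid oxidation (-0.73) being added; same-numbered arrays did not deviate together (correlations -0.02 to 0.01 over probe sets and -0.11 to 0.03 over gene table rows), and no control array correlated best with its own number. The other settings of these counts gave 0.

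The number of called lists was 0 with an estimated correlation and 0 with fry, and 1 to 6 with an array left out, lowest without control replicate 2. Both tests leave the medians as they are (-1.63 TCA cycle, -0.87 electron transport chain, -0.78 glycolysis, 0.75 extracellular matrix, 0.39 cytokines) and end all 5 calls, with fry adjusted p from 0.127 to 0.381. With an array left out, medians ranged from -1.99 to -0.997 for the TCA cycle, called each time, from -1.34 to -0.66 for electron transport, from -1.60 to -0.68 for glycolysis, from 0.32 to 1.33 for matrix and from 0.27 to 0.55 for cytokines. The ranges were -1.31 to -0.29 for fatty acid oxidation, -0.67 to -0.18 for mature adipocyte genes, -1.17 to -0.39 for thermogenesis and -1.04 to 0.38 for lipogenesis. Without control replicate 1 the matrix call was lost. Without control replicate 2 the calls of electron transport, glycolysis, matrix and cytokines were lost. The cytokine call was also lost without control replicate 3 or Nr2f2-deleted replicate 2, and with array weights (0.33). Fatty acid oxidation was called without control replicate 3, with array weights (-0.89), and above the median signal or with joined rows (-0.75). Mature adipocyte genes were called without control replicate 3 or Nr2f2-deleted replicate 3. Quantile normalization moved the medians of electron transport to -0.52, fatty acid oxidation to -0.42 and mature adipocyte genes to -0.03, with no call changed. Glycolysis had -1.20 above the median signal and -0.50 with the trend removed, and mature adipocyte genes -0.07 with the trend removed. Lipogenesis, never called, turned to 0.32 with quantile normalization, 0.13 with the trend removed, 0.38 without control replicate 2 and 0.25 without Nr2f2-deleted replicate 2. Ucp1 ranged from -0.37 to 0.54 with an array left out, and turned without Nr2f2-deleted replicate 3. The cause was not tested for these losses and turns. With dim rows or dim members (below the median) left out, the cytokine list had fewer than 5 members and no value. Lists and named genes have no value on the probe-set table, which has no names, and Nr2f2 has none under any setting. Signal over background limits all of this: exon control probe sets exceeded intron ones with a probability of 0.581 to 0.602.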

Other observations

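Gene families outside the fixed lists were picked after their values had been seen, and their tests were chosen then too, as were the tests of array quality, of shared variation and of other splits of the arrays. The cytosolic ribosomal proteins had a median log2 difference of 0.20, with 26 of 41 higher in the deleted cells. Their camera p was 0.0873 (limma adjusted p = 0.265 over the families tested). The proteasome subunits had a median of -0.62, with 7 of 9 lower. Their camera p was 0.150 (limma adjusted p = 0.265). Mitochondrial ribosomal proteins had a median of -0.28 over 12 genes, and the chemosensory receptors, taken as unexpressed genes, 0.04 over 66 genes. No family passed, and whether any moved as a group stays open.

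Without control replicate 3, rows past the adjusted threshold in the gene table included, on the lower side, Pdhb (-5.19), Uqcrc1 (-5.01), Ndufb11 (-4.73, with a deleted mean below the receptor percentile of 6.73), Cycs (-4.55) and the mitochondrial pyruvate carrier gene Mpc1 (-3.23). On the higher side they included S100a6 (4.58), Col1a2 (3.81), Fbln2 (2.75) and Csf1 (2.53). Control replicates 1 and 2 lay below that percentile for Fbln2 (6.48 and 5.76) and Csf1 (4.85 and 4.64). For S100a6 they were at 7.24 and 6.19. The sizes of these 3 differences depend on the background. All genes in this paragraph are named after their values were seen, and an array was left out because of where it lay, so these values describe what 5 arrays give.

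Control replicate 3 lay with the deleted arrays on the first principal component. On the second component of the gene table (22.35) it lay apart from the deleted arrays (-11.86 to -3.08) and from the other controls (-1.28 and 0.36). In the probe-set table its second score lay within the range of the deleted arrays (-13.79 against -15.18 to 20.53). It also lay between the other controls, at -40.17 and 53.03, so that score does not place control replicate 3 with either group. The 100 probe sets that most separated the other controls (position 0) from pairs of deleted arrays (position 1) were taken. On them the median positions of control replicate 3 were 0.963, 1.01 and 1.01, against 0.79 to 0.98 for a deleted array left out. Neither other control was left out in this way, so there is no reference for where a control would fall. Counts in the gene table follow its label: rows with an unadjusted p under 0.05 numbered 340 as labelled and 106 to 151 with control replicate 3 exchanged for a deleted array. That table was selected by a rule not given in the sources used here, possibly on the labelled groups, and in the probe-set table such counts were 1098 as labelled and 1061 to 1121 exchanged. A deleted culture under a control label therefore cannot be told apart from a control that differentiated less, and Nr2f2 was not analysed here. If a poorer array only lowers signals, one is argued against for the matrix genes alone. The matrix list mean of control replicate 3 exceeded the higher of the other controls by 2.12, against 0.368 between those. That premise was not tested, and the comparison was written after its values had been seen. For the dimmer metabolic genes a poorer array cannot be told apart. The exon to intron separation of control replicate 3, 0.591, was within the range of the others (0.581 to 0.602). Its 4 hybridisation controls, however, were the lowest of all arrays. No test of differentiation was run, so that explanation stays open.

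The 5 called lists may reflect variation shared by the members of a list. Camera also compared each list with other rows of a selected table, so the calls cannot be separated from that selection. Simulated tables with no shift and correlated members had a called list in 93% of draws, and 5 or more in 11%. Each simulated list varied on its own, whereas the real metabolic and matrix lists moved together in control replicate 3. The 11% therefore does not measure how often 5 calls arise together without a shift. With an estimated correlation, 0 lists passed in the real data. That correlation was 0.062 for the cytokine list, against 0.374 to 0.438 for the other called lists. The low value does not make the cytokine call firmer, since 3 of its 5 members had both means below the receptor percentile. The call was lost with an estimated correlation, with fry and with array weights. It was also lost without control replicate 2, control replicate 3 or Nr2f2-deleted replicate 2. The test with an estimated correlation has little power here: with a TCA cycle list truly lower by 2 on the log2 scale, it called the list in 16% of draws. A trend of the difference with signal level was argued against, as 5 of 5 lists were still called after its removal. Of the 10 splits of the 6 arrays, 4 called as many lists, with 5 for the real split and up to 7 for the others, and 10 splits are too few for a share under 0.05. The splits with 7 were the 3 that exchange control replicate 3 for a deleted array, which points to a structure of the arrays. A response to the deletion stays open as well. The deleted samples alone received Cre, and the design does not separate its presence from the deletion.

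An excess of small p-values over chance may lie in the bright probe sets, but splits that mix the groups gave a surplus there too. The share with an unadjusted p under 0.05 was 12.2% in the brightest 10% and 4.94% over all, a ratio of 2.48, although 272 of the 1098 such probe sets lay in that part. The brightest 10% held 272 such probe sets as labelled, 269 to 305 in the 3 splits that exchange control replicate 3 for a deleted array, and 163 to 199 in the other 6 splits. Over all probe sets those other 6 splits had 894 to 1098. The bright part thus held more than its 10% in every split, and the ratio does not single out the labelled groups. At an adjusted p under 0.05 the real count was 0 and the highest other 0; any split reaches 0, so the count of 10 of 10 splits decides nothing. For gene table rows with an unadjusted p under 0.05, 1 of 10 splits, the real one, reached 340, and the highest other was 151. Again 10 splits are too few for a share under 0.05, and the rows were selected beforehand.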
